A study of Mus musculus with 12 samples.

How the data were processed

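Polyadenylated RNA of NIH/3T3 mouse fibroblasts was sequenced in 12 libraries, 3 for each of 4 treatments of 8 h: vehicle (DMSO), 200 nM carfilzomib (CFZ), 5 µM doxorubicin (DOX) and both drugs (CFZ-DOX). Groups and replicate numbers were taken from the sample titles. The authors deposited 1 table of raw counts, whole numbers of reads per Ensembl gene, with the chromosome, start, end, strand and exon length of each gene. Per the submitters' processing notes, Trimmomatic 0.39, STAR 2.7.9a and featureCounts of Subread 2.0.2 were used with the mouse build GRCm39. The annotation release, the strand setting of the counting and the handling of read pairs were not given in the sources used here, so reads of overlapping and antisense genes may be shared between them. Coordinates are those of the deposited table.

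The table held 56980 gene IDs. Symbols were taken from an older annotation of mouse genes, used for names only, which matched 52073 IDs (91.4%). The 4907 IDs without a symbol held 0.25 to 0.72% of the counts of a library and stayed in the tests. Total counts per library were 28278879 to 42033993. A count of 0 was read as allowing up to 3 counts of the library total, 0.0714 to 0.106 CPM, which covers counting error only.

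Replicates were compared before they were averaged. The chi-square of their counts per degree of freedom was 13.86 to 32.47 within DMSO and CFZ and 51.87 to 125.3 within DOX and CFZ-DOX. Their Pearson r across genes on log CPM was 0.974 to 0.993. No pair differed by as little as sampling noise, and replicates with doxorubicin differed more than those without. CPM values are normalised with the TMM factors and are given as mean ± SD of 3 libraries, except that bounds of 0 counts and sums over receptor genes are CPM of the library total.

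Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total count 15), which left 16648. They were tested with edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3, robust fit, TMM scaling) in 1 model of all 12 libraries with a mean per group, and p-values were adjusted by Benjamini-Hochberg. A gene was called at an adjusted p under 0.05. A prior count of 0.125 was used for log2 fold changes. Standard errors (SE) are the absolute log2 fold change divided by the square root of its F statistic. They were not estimated directly and are only approximate for genes with almost no counts in a group. The comparisons were each treatment against DMSO, CFZ-DOX against CFZ and against DOX, and the interaction of CFZ and DOX, the log2 difference between the effect of both drugs and the sum of their single effects.

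The design, the alternatives, 26 gene lists and the rule for named genes were fixed before the data were examined. The lists cover the proteasome, heat shock, the integrated stress response, the unfolded protein response, NRF2 and p53 targets, mitosis, DNA replication, histones, immediate early, NF-κB, interferon and cholesterol genes, extracellular matrix and contractile genes. They also cover autophagy, the BCL2 family, ribosomal protein, respiratory chain and mitochondrially encoded genes, and markers of 6 cell types. The 23 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 (limma 3.58.1), and again with an estimated correlation and with fry. The text names genes chosen for these drugs (a result for 1 of them is not reported here), the 6 highest and 6 lowest called genes of each comparison with a mean of at least 5 CPM, a proper symbol and, except for the interaction, no overlap between the groups, and up to 4 called members of a list in its main direction and 2 in the other. Chance gives no overlap in 10% of genes with 3 libraries against 3. A list with no called member is illustrated by its most abundant members.

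The alternatives held 4 scalings besides TMM: DESeq2-type size factors, library size, upper quartile and the ribosomal protein genes. Calls that agree in all 5 were counted only after ribosomal protein genes were seen to take a larger part of the counts with doxorubicin. The median log2 fold change of all genes moved under ribosomal scaling by −0.07 for CFZ, −0.87 for DOX, −1.63 for CFZ-DOX against DMSO, −1.56 against CFZ, −0.76 against DOX and −0.70 for the interaction. Under upper-quartile scaling it moved by 0.38 for DOX, 0.50 and 0.54 for CFZ-DOX against DMSO and CFZ, 0.12 against DOX and 0.16 for the interaction. Other alternatives were DESeq2 1.42.0, limma-voom, other filters, a stricter adjusted p, a test against a 1.5-fold change, only the 6 libraries compared, the replicate number as a block, and leaving out each library in turn.

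Libraries with the same replicate number deviated together from their group means in 3 comparisons, with r across genes of 0.38, 0.30 and 0.42 for CFZ and DMSO, 0.25, 0.26 and 0.21 for DOX and DMSO and 0.58, 0.35 and 0.65 for CFZ-DOX and DOX. The pairing comes from these correlations and not from the labels, and values with the replicate number as a block are given beside a result of these comparisons where they change its call.

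The scripts were tested on simulated counts of the 16648 genes with 200 of them changed. Changes of 4-fold were recovered in 95.5% to 98.5% of genes in the 5 comparisons of groups and in 86.4% for the interaction, changes of 2-fold in 61.2 to 79.1% and 19.4%, and changes of 1.5-fold in 13.4 to 19.4% and 1.49%, with 4 to 9 false calls.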

Results

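NIH/3T3 is an immortalised line of mouse embryonic fibroblasts. Its polyadenylated RNA was sequenced after 8 h with vehicle (DMSO), with 200 nM carfilzomib (CFZ), with 5 µM doxorubicin (DOX) or with both drugs together (CFZ-DOX). Carfilzomib is an irreversible inhibitor of the proteasome, and doxorubicin is an anthracycline that intercalates into DNA and poisons topoisomerase II. Each group held 3 libraries, which are named here by group and replicate number. The design asks how expression after each drug and after the combination compares with vehicle. Nothing in the labels says that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

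The 12 libraries held 28278879 (CFZ-DOX 3) to 42033993 (DOX 1) counts, with 31024213 to 40134000 in the DMSO, 30460507 to 39685017 in the CFZ, 32351317 to 42033993 in the DOX and 28278879 to 38327183 in the CFZ-DOX libraries. Cdkn2a, the tumour suppressor locus that this line is known to lack, had 0 counts in all 12 libraries, which allows up to 0.106 CPM (counts scaled to the library total) in the smallest. Libraries with doxorubicin held more genes with at least 1 count: 26010 ± 713 with DOX and 26043 ± 510 with CFZ-DOX, against 21859 ± 436 with DMSO and 21730 ± 457 with CFZ (SD, n = 3). Cytosolic ribosomal protein genes took 4.06 ± 0.179% of counts with DMSO, 4.08 ± 0.253% with CFZ, 6.85 ± 0.29% with DOX and 10.0 ± 0.332% with CFZ-DOX. The first principal component of log CPM held 75.9% of the variance and parted the libraries with doxorubicin from those without, and the second held 8.54% and parted CFZ from DMSO. On the third, with 4.64% of the variance, DOX 3 at −60.6 lay apart from DOX 1 and DOX 2 (6.7 and −7.1), and CFZ-DOX 3 at −24.6 apart from CFZ-DOX 1 and CFZ-DOX 2 (43 and 32.6), with the DMSO and CFZ libraries between −9 and 10.

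**Figure D1:**
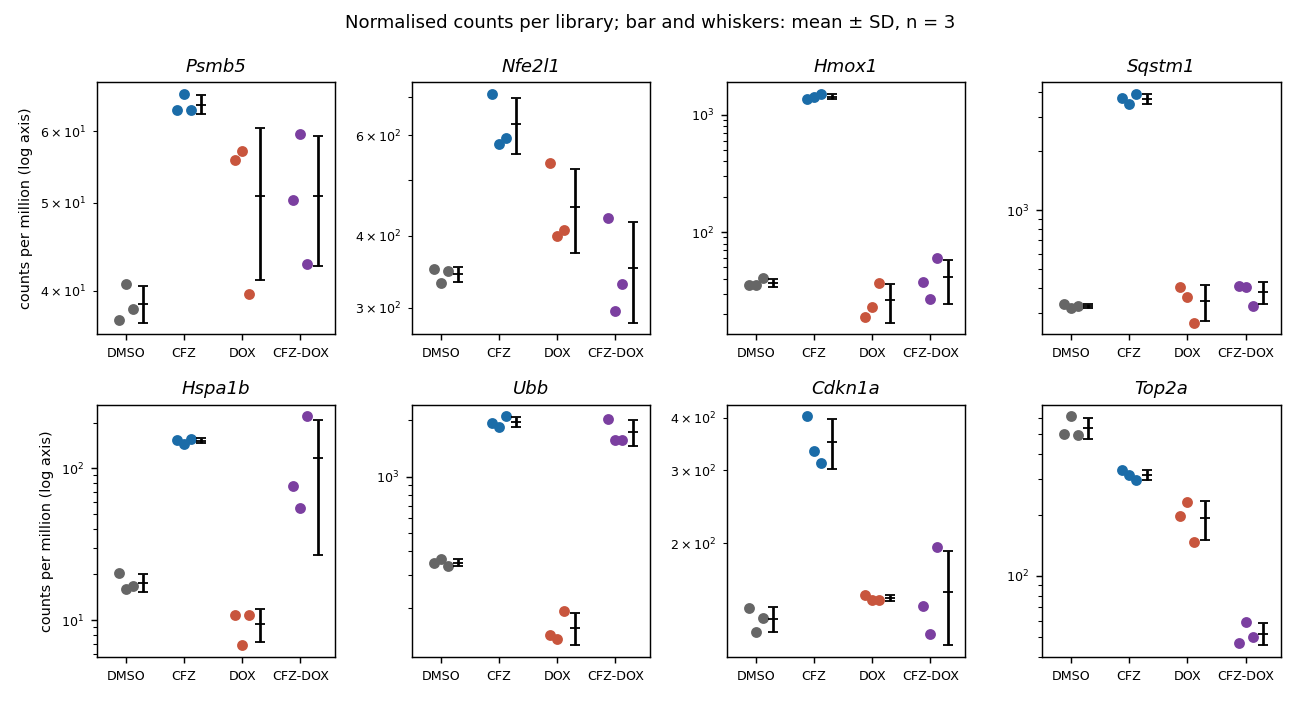
TMM-normalised CPM of 8 genes in each of the 12 libraries on log axes, by treatment, with the mean and SD of 3 libraries beside the points. Hmox1 and Sqstm1 were high with CFZ and near the DMSO level in the libraries with both drugs, while Ubb was high in all 3 CFZ and all 3 CFZ-DOX libraries.

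After 8 h of carfilzomib alone, genes of protein quality control rose. Of 42 proteasome subunit and assembly genes 35 rose, of 24 heat shock genes 21 rose, and of 24 targets of NRF2, the transcription factor of the oxidative stress response, 20 rose. Targets of p53 rose too (23 of 30), and mitotic genes fell (26 of 30). Over all 16648 genes tested, 2402 were higher and 2395 lower than with DMSO, 982 and 1083 of them by at least 2-fold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The spread was estimated over all 12 libraries. Fitted to the 6 libraries of this comparison alone, 3918 genes were higher and 4007 lower.

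The highest named gene was Hmox1 (ENSMUSG00000005413, GRCm39 chromosome 8, 75820249 to 75827217, plus strand), which encodes the haem-degrading enzyme heme oxygenase 1. It rose 38.4-fold, from 37.1 ± 3.04 to 1426 ± 73.2 CPM (SD, n = 3; edgeR log2 fold change 5.26, SE 0.31, adjusted p = 9.91e-08). Atf3, a stress-induced transcription factor (edgeR log2 fold change 4.65, SE 0.41, adjusted p = 2.95e-06), Calr3 (log2 fold change 4.25, SE 0.19, adjusted p = 2.19e-08) and Osgin1 (log2 fold change 4.05, SE 0.35, adjusted p = 2.08e-06) followed. Next came Napb (edgeR log2 fold change 3.78, SE 0.18, adjusted p = 2.19e-08) and the aldehyde oxidase Aox1 (log2 fold change 3.64, SE 0.34, adjusted p = 4.43e-06). Here and below, the largest changes are those among called genes with a mean of at least 5 CPM, a proper symbol and, except for the interaction, no overlap between the groups. The largest falls were those of the peptide hormone gene Apln (edgeR log2 fold change −4.15, SE 0.25, adjusted p = 1.08e-07), the growth arrest gene Gas1 (log2 fold change −3.39, SE 0.32, adjusted p = 5.52e-06) and the cytochrome P450 Cyp1b1 (log2 fold change −3.07, SE 0.44, adjusted p = 0.000143). Siglecg (edgeR log2 fold change −3.00, SE 0.27, adjusted p = 3.22e-06), Smad6 (log2 fold change −2.80, SE 0.33, adjusted p = 2.93e-05) and the chemokine gene Cxcl12 (log2 fold change −2.85, SE 0.77, adjusted p = 0.0163) fell next. The call of Cxcl12 was lost without CFZ 2, CFZ 3 or DMSO 1, with adjusted p of 0.0761, 0.0728 and 0.0506, and the log2 fold change of Cyp1b1 was −3.75 without CFZ 1.

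Among heat shock genes, Cryab, which encodes a small heat shock protein, rose 8.73-fold, Dnajb1, a co-chaperone of HSP70, 8.58-fold, and the inducible HSP70 genes Hspa1b and Hspa1a 8.58-fold and 8.53-fold (edgeR adjusted p = 1.06e-06, 3.81e-06, 0.000123 and 0.000261). Hspa1a and Hspa1b are near-identical copies on chromosome 17 whose reads cannot be parted with certainty. Ubb, which encodes ubiquitin, rose 5.62-fold (edgeR adjusted p = 5.62e-07). Proteasome genes rose by less: Psmb3 3.27-fold, Psmc4 3.2-fold and Psmd4 3.09-fold (edgeR adjusted p = 8.46e-07, 1.52e-06 and 2.81e-06). Psmb5, which encodes the catalytic subunit that carfilzomib binds, rose 1.66-fold (edgeR adjusted p = 0.00286), and Nfe2l1, the transcription factor that induces proteasome genes, 1.83-fold (adjusted p = 0.00175). The only members that fell were the assembly chaperones Psmg1 (edgeR log2 fold change −0.58, SE 0.19, adjusted p = 0.0326) and Psmg2 (log2 fold change −0.49, SE 0.15, adjusted p = 0.0239). Both of these calls were lost whenever 1 of the 6 libraries compared was left out. Adjusted over the list alone, 37 proteasome genes rose and 2 fell, and 22 heat shock genes rose.

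The autophagy receptor gene Sqstm1 rose 11.4-fold to 3705 ± 218 CPM (edgeR log2 fold change 3.52, SE 0.19, adjusted p = 4.99e-08) and Gabarapl1 4.27-fold, among 11 of 21 autophagy genes that rose and 1 that fell (12 and 2 adjusted over the list alone). The NRF2 targets included the cystine transporter Slc7a11 (edgeR log2 fold change 3.33, SE 0.16, adjusted p = 2.19e-08) and the sulfiredoxin Srxn1 (log2 fold change 2.79, SE 0.14, adjusted p = 2.19e-08), and 20 of 24 rose adjusted over the list alone. Of 30 genes of the integrated stress response 13 rose and 3 fell (15 and 3 adjusted over the list alone). They included Ppp1r15a (edgeR log2 fold change 2.87, SE 0.26, adjusted p = 3.14e-06), Ddit3, which encodes the transcription factor CHOP (log2 fold change 1.95, SE 0.27, adjusted p = 0.000113), and, in the other direction, Atf5 (log2 fold change −1.19, SE 0.28, adjusted p = 0.00529). Of 24 genes of the unfolded protein response of the endoplasmic reticulum 11 rose and 2 fell (12 and 2 adjusted over the list alone), with the chaperone gene Hspa5 rising 3.59-fold and Dnajb9 3.2-fold (edgeR adjusted p = 2.94e-05 and 0.000297). Among NF-κB and inflammatory genes 15 of 20 rose (16 adjusted over the list alone). Among them were the chemokine gene Ccl2 (edgeR log2 fold change 3.27, SE 0.55, adjusted p = 0.00132; 2.42 without CFZ 1) and Ptgs2, which encodes cyclooxygenase 2 (log2 fold change 2.88, SE 0.38, adjusted p = 6.89e-05).

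The p53 targets that rose included the cell cycle inhibitor Cdkn1a (edgeR log2 fold change 1.41, SE 0.17, adjusted p = 3.63e-05) and the p53 ubiquitin ligase gene Mdm2 (log2 fold change 2.27, SE 0.19, adjusted p = 1.77e-06). The death receptor gene Fas (edgeR log2 fold change 3.59, SE 0.35, adjusted p = 6.84e-06) and Pmaip1, which encodes NOXA (log2 fold change 2.45, SE 0.24, adjusted p = 7.56e-06), rose too. Trp53 itself rose 1.58-fold (edgeR adjusted p = 0.00163), and 24 of the 30 targets rose adjusted over the list alone. The mitotic kinase gene Plk1 fell to 23.4 ± 3.33 CPM from 98.7 ± 13.7 (edgeR log2 fold change −2.08, SE 0.24, adjusted p = 2.47e-05). The cyclin gene Ccna2 (edgeR log2 fold change −2.03, SE 0.24, adjusted p = 3.35e-05) fell, as did Top2a, 1 of the 2 genes for the target of doxorubicin (log2 fold change −0.78, SE 0.17, adjusted p = 0.00354). The other, Top2b, was not called (edgeR log2 fold change −0.16, SE 0.11, adjusted p = 0.334). Of 37 DNA replication genes 24 fell, Tk1 and Ccne1 among them, as did 10 of 45 replication-dependent histone genes (24 and 9 adjusted over the list alone), against 29 of 30 mitotic genes. Of 13 BCL2 family genes 5 fell and 2 rose (6 and 2 adjusted over the list alone), with the death-promoting Bmf and the protective Bcl2 both lower (edgeR adjusted p = 0.00112 and 0.000575). The efflux pump genes Abcb1a and Abcb1b, whose product exports doxorubicin, rose 3.18-fold and 1.62-fold (edgeR adjusted p = 0.00274 and 0.00812). The metallothionein genes Mt1 and Mt2 and Gapdh were not called (edgeR adjusted p = 0.636, 0.517 and 0.983).

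Of 76 cytosolic ribosomal protein genes none was called by edgeR with TMM scaling, 0 at an unadjusted p under 0.05, 0 by limma-voom and 1, higher, by DESeq2, with Rplp0 at 1734 ± 49.1 CPM with DMSO and 2021 ± 88.0 with CFZ (edgeR adjusted p = 0.412). Of 9 tested fibroblast markers 3 fell and none rose in edgeR, at an unadjusted p under 0.05 and with DESeq2 and limma-voom too (3 and 0 adjusted over the list alone), led by the growth factor receptor gene Pdgfrb (edgeR log2 fold change −2.05, SE 0.24, adjusted p = 2.75e-05). Immediate early genes moved both ways (8 rose and 3 fell of 26; 8 and 4 adjusted over the list alone), as did interferon-stimulated genes (3 and 2 of 15; 4 and 2) and genes of cholesterol synthesis (7 and 4 of 25; 7 and 4).

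Set against all other genes with camera at a preset correlation of 0.01, 12 of 23 lists were called for CFZ, 8 up and 4 down. With an estimated correlation, 6 held: heat shock and NRF2 (both adjusted p = 0.00238), autophagy (0.0403), and the integrated stress response, p53 targets and mitosis (all 0.0461). The calls of the proteasome list (adjusted p = 0.08 with an estimated correlation), DNA replication (0.0948), NF-κB (0.146), histones (0.247), the unfolded protein response (0.415) and fibroblast markers (0.542) were lost. Other splits of the same 6 libraries gave up to 16 lists. Here and below, each other split kept a part of the treatment difference, since its sides held unequal numbers of each treatment. The list counts of other splits therefore do not measure chance, and the number of lists called has no such measure beside it. Scaling to library size gave 1502 genes higher and 2547 lower, and scaling to ribosomal protein genes 1444 and 2226, while 1352 and 1943 were called the same way under all 5 scalings.

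Doxorubicin alone changed most of the genes tested. With DOX 6010 genes were higher and 5213 lower than with DMSO, 3890 and 3209 of them by at least 2-fold (edgeR quasi-likelihood test, adjusted p under 0.05). Transcripts of the cytosolic ribosome and of the nuclear-encoded respiratory chain took a larger part of the counts, mitotic genes fell, and some genes with almost no counts in DMSO rose. The direction of a large part of these calls depends on scaling: counts scaled to ribosomal protein genes put the median log2 fold change of all genes 0.87 lower, with 2235 genes higher and 9082 lower, and upper-quartile scaling gave 8069 and 3713. Under all 5 scalings 2235 genes were higher and 3713 lower, and a gene is said below to have moved in all 5 scalings where it belongs to these.

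The largest rises in all 5 scalings came from genes with almost no counts in DMSO. Btnl9 (ENSMUSG00000040283, GRCm39 chromosome 11, 49056412 to 49077986, minus strand), a butyrophilin-like gene, went from 0.0634 ± 0.0351 to 13.2 ± 5.09 CPM (SD, n = 3; edgeR log2 fold change 7.68, SE 0.51, adjusted p = 3.3e-08). The bile acid transporter gene Slc10a1 (ENSMUSG00000021135, chromosome 12, 80999957 to 81015479), usually expressed in liver, went from 0.103 ± 0.134 to 10.9 ± 2.66 CPM (edgeR log2 fold change 6.76, SE 0.50, adjusted p = 8.16e-08; 8.56 without DMSO 3). Slc23a3 (edgeR log2 fold change 5.66, SE 0.44, adjusted p = 1.14e-07) and Slc43a2 (log2 fold change 5.09, SE 0.39, adjusted p = 1.06e-07) followed. Next came Rhof (edgeR log2 fold change 4.70, SE 0.28, adjusted p = 1.85e-08) and Aoc3 (log2 fold change 4.59, SE 0.37, adjusted p = 1.42e-07). The largest falls in all 5 scalings were those of the transcription factor gene Cebpb (15.3 ± 3.14 to 0.459 ± 0.173 CPM; edgeR log2 fold change −5.04, SE 0.38, adjusted p = 8.43e-08) and of Zbtb45 (log2 fold change −4.54, SE 0.22, adjusted p = 6.44e-09). Ccnq (edgeR log2 fold change −4.42, SE 0.28, adjusted p = 2.63e-08) and Fignl1 (log2 fold change −4.23, SE 0.23, adjusted p = 1.02e-08) fell next. Champ1 (edgeR log2 fold change −4.09, SE 0.15, adjusted p = 8.77e-10) and the zinc finger gene Zfp90 (log2 fold change −4.03, SE 0.22, adjusted p = 1.02e-08) completed the 6.

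Targets of p53 parted: 15 of 30 rose and 6 fell (15 and 6 adjusted over the list alone), 8 and 5 of them in all 5 scalings. Pmaip1 rose 11.8-fold to 53.3 ± 14.1 CPM (edgeR log2 fold change 3.56, SE 0.25, adjusted p = 5.49e-08). Btg2 (edgeR log2 fold change 2.22, SE 0.46, adjusted p = 0.000917) and Fas (log2 fold change 1.96, SE 0.34, adjusted p = 0.000145) rose too, while Phlda3 (log2 fold change −2.66, SE 0.21, adjusted p = 1.3e-07) and Plk2 (log2 fold change −1.91, SE 0.32, adjusted p = 0.000104) fell. Cdkn1a stood at 148 ± 2.49 CPM against 132 ± 8.90 with DMSO (edgeR adjusted p = 0.388), with a log2 fold change of 0.17 that turned to −0.71 under ribosomal scaling. Mdm2 stood at 89.5 ± 14.9 against 116 ± 10.7 CPM (edgeR adjusted p = 0.0775, and 0.0226 with the replicate number as a block), and Trp53 was not called (adjusted p = 0.239). Under ribosomal scaling both were lower, with log2 fold changes of −1.22 and −1.04.

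With TMM scaling, genes of proteostasis moved both ways. Of 24 heat shock genes 9 fell and 4 rose (9 and 4 adjusted over the list alone). The constitutive chaperone gene Hspa8 fell to 278 ± 76.2 from 1268 ± 117 CPM (edgeR log2 fold change −2.19, SE 0.21, adjusted p = 7.39e-07). Ptges3 fell 3.97-fold and Dnajb1 2.67-fold (edgeR adjusted p = 3.33e-07 and 0.000338). Ubb fell 2.22-fold (edgeR adjusted p = 4.82e-05). Hspa1b (edgeR adjusted p = 0.0592) and Hmox1 (0.114) were not called without the replicate block and were lower with it (adjusted p = 0.0211 and 0.0164). Both were lower under ribosomal scaling too (adjusted p = 0.00508 and 0.0061), as was Hspa1b with DESeq2 (0.0379) and Hmox1 without DOX 3 (0.0186). Sqstm1 was not called (edgeR adjusted p = 0.666), with a log2 fold change of 0.09 that turned to −0.82 under ribosomal scaling. Of 42 proteasome genes 20 rose and 10 fell (20 and 10 adjusted over the list alone), but in all 5 scalings none rose and 4 fell. Of 30 genes of the integrated stress response 9 fell and 7 rose (9 and 5 adjusted over the list alone). Under ribosomal scaling 21 heat shock, 35 proteasome and 25 integrated stress response genes were lower and at most 1 of each list higher. Trib3 (edgeR log2 fold change −3.58, SE 0.24, adjusted p = 4.18e-08), Atf4, the transcription factor of this response (log2 fold change −3.38, SE 0.19, adjusted p = 1.03e-08), and Chac1 (log2 fold change −3.11, SE 0.30, adjusted p = 8.39e-07) fell in all 5 scalings.

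Of 26 immediate early genes 12 fell, all of them in all 5 scalings, and 9 rose, 6 in all 5 (12 and 9 adjusted over the list alone). Klf6 (edgeR log2 fold change −3.52, SE 0.19, adjusted p = 1.04e-08) and Klf2 (log2 fold change −3.18, SE 0.26, adjusted p = 1.92e-07) fell. Fosb (edgeR log2 fold change 4.41, SE 0.31, adjusted p = 5.33e-08) and Nr4a3 (log2 fold change 3.62, SE 0.30, adjusted p = 2.14e-07) rose. In the BCL2 family, the protective Mcl1 (edgeR log2 fold change −2.81, SE 0.27, adjusted p = 6.6e-07) and Bcl2l1 (log2 fold change −1.56, SE 0.18, adjusted p = 3.94e-06) fell. Bcl2l11, which encodes the death-promoting BIM, rose (edgeR log2 fold change 2.19, SE 0.18, adjusted p = 1.51e-07). Of 13 tested members 5 rose and 6 fell, the same counts as adjusted over the list alone (2 and 7 under ribosomal scaling). Of 25 genes of cholesterol synthesis 11 fell and 7 rose (as many adjusted over the list alone, and 18 and 2 under ribosomal scaling), with Insig1, Sqle and Hmgcs1 down 5.84-fold, 4.52-fold and 4.27-fold (edgeR adjusted p = 7.13e-08, 1.24e-05 and 2.43e-05).

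Of 30 mitotic genes 23 fell and none rose in edgeR, at an unadjusted p under 0.05 and with DESeq2 and limma-voom too. Ect2 (edgeR log2 fold change −2.69, SE 0.26, adjusted p = 7.99e-07), Ccna2 (log2 fold change −2.62, SE 0.25, adjusted p = 6.63e-07) and the proliferation marker Mki67 (log2 fold change −2.05, SE 0.15, adjusted p = 6.52e-08) were among the lowest. Top2a fell 2.8-fold (edgeR log2 fold change −1.49, SE 0.17, adjusted p = 4.43e-06), and Top2b was not called (adjusted p = 0.064) but was lower with DESeq2 (adjusted p = 0.0459), library size (0.0325) and ribosomal scaling (2.19e-05). Of 37 DNA replication genes 17 fell and 6 rose (under ribosomal scaling 35 fell and none rose), with the origin licensing genes Cdc6 and Cdt1 down 5.99-fold and 5.43-fold (edgeR adjusted p = 3.02e-07 and 3.54e-07), and adjustment over the list alone gave the same counts for both lists. Replication-dependent histone genes, whose mRNAs normally end in a stem-loop without a poly(A) tail, went the other way: 36 of 45 rose and 2 fell (as many adjusted over the list alone), 22 and 2 in all 5 scalings. The list held 70 genes, and some of those tested, Hist1h3b among them, passed the filter only through their counts with doxorubicin. For such genes a rise was fixed by the filter. The histone median of 1.92 stood against 1.4 in the lowest of 5 groups of all tested genes by level. Hist1h3b rose from 0.0602 ± 0.00771 to 1.90 ± 0.462 CPM (edgeR log2 fold change 4.89, SE 0.37, adjusted p = 1.01e-07). Hist1h2ac rose from 0.156 ± 0.0808 to 2.92 ± 0.576 CPM (edgeR log2 fold change 4.20, SE 0.37, adjusted p = 3.65e-07), while Hist1h2ao fell (log2 fold change −2.82, SE 0.37, adjusted p = 1.25e-05). Histone genes are near-identical copies of one another, so their reads may be split between them.

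Of 76 cytosolic ribosomal protein genes 75 rose and 1 fell, with a median log2 fold change of 0.91, and of 79 nuclear genes of the respiratory chain 74 rose (median 0.93) and none fell in edgeR, at an unadjusted p under 0.05 and with DESeq2 and limma-voom too, with as many calls adjusted over each list alone. Rpl31 rose 2.27-fold and Cox6a1, a subunit of cytochrome oxidase, 2.36-fold (edgeR adjusted p = 0.000111 and 6.95e-05). When counts were scaled to the ribosomal protein genes themselves, 1 of them was higher and 6 lower, and 4 of the respiratory chain genes were higher and 9 lower, so these rises are relative to other transcripts. The same held for Gapdh, at 1647 ± 144 CPM with DMSO and 2936 ± 495 with DOX (edgeR log2 fold change 0.83, SE 0.19, adjusted p = 0.00117), whose log2 fold change turned to −0.06 under that scaling. Of the 13 genes encoded in mitochondria 5 rose (3 adjusted over the list alone), while under ribosomal scaling 6 fell and none rose.

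Some markers of other cell types rose with DOX. Of 5 tested haematopoietic markers 5 rose and of 5 muscle markers 4 (as many adjusted over each list alone), 2 of each in all 5 scalings. The lists held 12 and 10 markers, and Cd79a and Ckm were tested only for their counts with doxorubicin, so that their rise was fixed by the filter. The list medians of 1.58 and 1.55 stood against 1.4 in the lowest of 5 groups of all tested genes by level. The B cell gene Cd79a went from 0.0697 ± 0.0158 to 3.87 ± 0.907 CPM (edgeR log2 fold change 5.73, SE 0.46, adjusted p = 1.53e-07). Of 3 tested epithelial markers 1 rose and 1 fell, of 4 endothelial markers 2 rose and of 2 adipocyte markers 1, and these lists were too short for a list test. The abundant leukocyte genes Ptprc and Tyrobp had 8 and 0 counts in the 3 DOX libraries together. Of 9 fibroblast markers 3 rose and 2 fell (2 and 2 adjusted over the list alone; none and 3 under ribosomal scaling), with Pdgfra falling 4.6-fold (edgeR adjusted p = 9.71e-06). Of 30 extracellular matrix genes 15 rose and none fell in edgeR, at an unadjusted p under 0.05 and with DESeq2 and limma-voom too (12 rose adjusted over the list alone), 1 of them in all 5 scalings, and of 17 contractile genes 12 rose and 2 fell (1 and 5 under ribosomal scaling).

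Camera at the preset correlation called 4 of 23 lists for DOX: ribosomal protein genes up (adjusted p = 1.35e-09, and adjusted p = 0.913 with an estimated correlation) and respiratory chain genes up (camera adjusted p = 6.48e-09, and adjusted p = 0.913 with an estimated correlation). The others were histones up (camera adjusted p = 3.64e-06, and adjusted p = 0.532 with an estimated correlation) and mitosis down (3.76e-05, and adjusted p = 0.913 with an estimated correlation). With the replicate number as a block it called 7. Other splits of the same 6 libraries gave up to 15 lists.

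**Figure D2:**
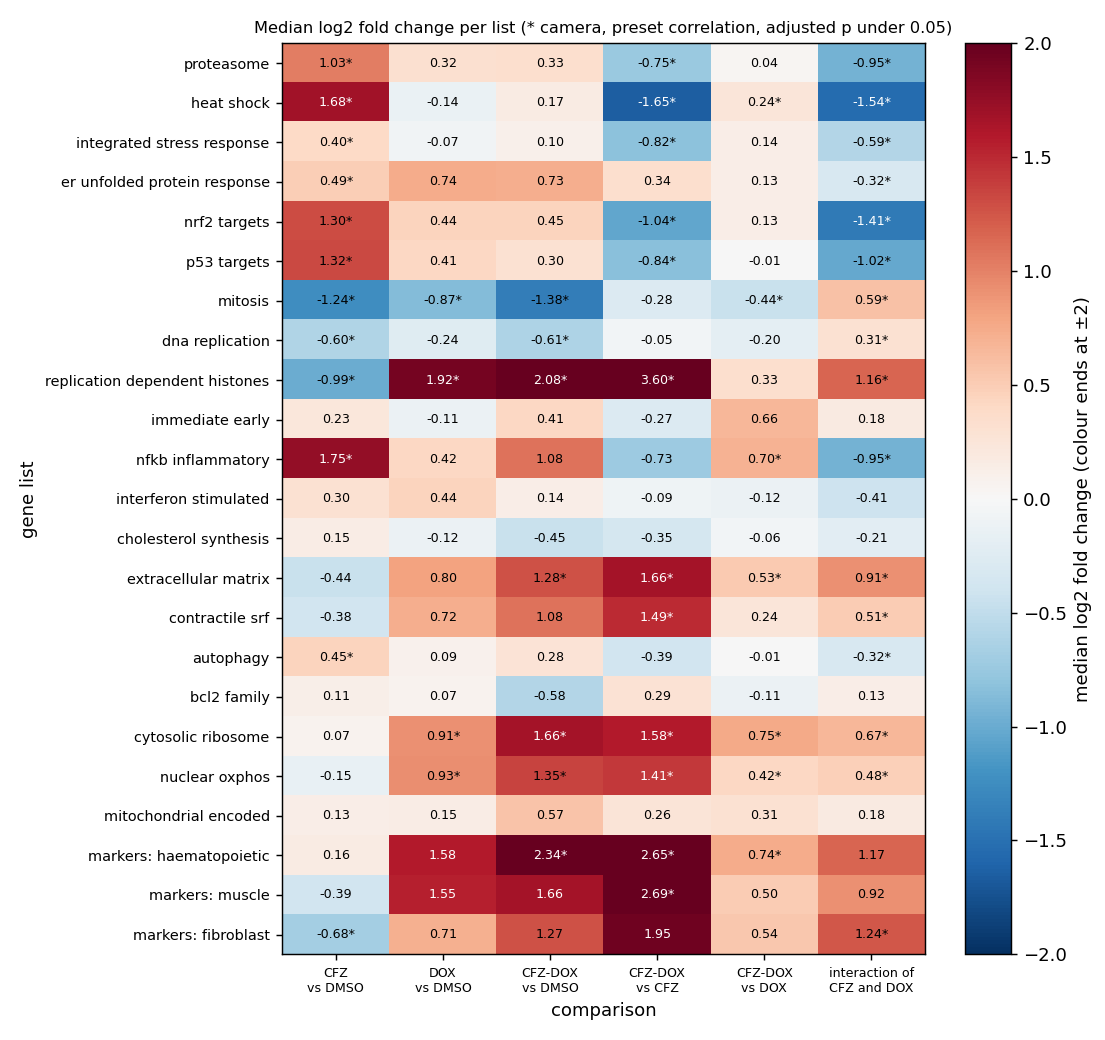
Median log2 fold change of the 23 gene lists with at least 5 tested members (rows) in the 6 comparisons (columns), with TMM scaling; colour runs from blue (lower) to red (higher), and an asterisk marks a camera call at the preset correlation. The heat shock row reads 1.68 for CFZ vs DMSO and 0.24 for CFZ-DOX vs DOX. Under ribosomal scaling the medians for DOX vs DMSO would lie about 0.87 lower, which turns the sign of positive medians below that size.

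With both drugs together the profile lay near that of doxorubicin. CFZ-DOX gave 6536 genes higher and 5942 lower than DMSO, 5090 and 4039 of them by at least 2-fold (edgeR quasi-likelihood test, adjusted p under 0.05). With TMM scaling, Ubb and some HSP70 genes were raised as with carfilzomib, while heme oxygenase, p62 (Sqstm1) and p21 (Cdkn1a) transcripts stood near their DMSO level. Mitotic genes and topoisomerase II were lower than with DMSO, and ribosomal protein genes took a larger part of the counts. Scaling to ribosomal protein genes moved the median log2 fold change by −1.63 and gave 1871 genes higher and 11377 lower, upper-quartile scaling gave 8469 and 4121, and under all 5 scalings 1871 were higher and 4121 lower.

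Slc10a1 (edgeR log2 fold change 7.22, SE 0.51, adjusted p = 2.59e-08; 9 without DMSO 3), Btnl9 (log2 fold change 7.06, SE 0.51, adjusted p = 3.26e-08) and Slc23a3 (log2 fold change 6.24, SE 0.44, adjusted p = 2.86e-08) rose most, each in all 5 scalings. Rhof (edgeR log2 fold change 5.82, SE 0.29, adjusted p = 2.37e-09), Jsrp1 (log2 fold change 5.44, SE 0.32, adjusted p = 7.6e-09) and Aoc3 (log2 fold change 5.09, SE 0.37, adjusted p = 3.47e-08) came next, again in all 5. Ccnq (edgeR log2 fold change −5.31, SE 0.31, adjusted p = 7.77e-09), Fignl1 (log2 fold change −5.25, SE 0.25, adjusted p = 2.32e-09) and Ccdc102a (log2 fold change −4.66, SE 0.31, adjusted p = 1.67e-08) fell most, in all 5 scalings. Zbtb45 (edgeR log2 fold change −4.43, SE 0.22, adjusted p = 2.37e-09), Cebpb (log2 fold change −4.41, SE 0.37, adjusted p = 1.09e-07) and Champ1 (log2 fold change −4.41, SE 0.15, adjusted p = 7.31e-10) followed, also in all 5.

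Ubb stood at 1719 ± 270 CPM, 4.94-fold above DMSO (edgeR log2 fold change 2.30, SE 0.18, adjusted p = 6.36e-08). Hspa1b rose 6.63-fold (edgeR log2 fold change 2.73, SE 0.41, adjusted p = 4.28e-05), with 220.5 CPM in CFZ-DOX 3 against 76.35 and 54.69 in the 2 others. Without CFZ-DOX 3 its log2 fold change was 1.89. Hspa1a rose likewise (edgeR log2 fold change 2.69, SE 0.47, adjusted p = 0.000123), with a log2 fold change of 1.66 without CFZ-DOX 3 and no call under ribosomal scaling. Hspa8 rose 2.23-fold (edgeR adjusted p = 0.000131) with a log2 fold change of 1.16 that turned to −0.49 under ribosomal scaling, and Ptges3 fell (edgeR log2 fold change −3.18, SE 0.18, adjusted p = 7.39e-09). Dnajb1 stood at 81.7 ± 36.5 CPM against 109 ± 10.7 and was not called (edgeR adjusted p = 0.171), although it was lower without CFZ-DOX 3 (adjusted p = 0.00165), with the replicate number as a block (0.0395) and under ribosomal scaling (0.00026). Of 24 heat shock genes 10 rose and 6 fell (as many adjusted over the list alone), and of 24 NRF2 targets 11 rose and 7 fell. Under ribosomal scaling 21 heat shock genes, 20 NRF2 targets and 41 of 42 proteasome genes were lower and at most 1 of each list higher. Hmox1 at 41.3 ± 16.8 CPM and Sqstm1 at 380.2 ± 47.8 were not called (edgeR adjusted p = 0.605 and 0.239), and their log2 fold changes of 0.16 and 0.23 turned to −1.44 and −1.42 under ribosomal scaling, while DESeq2 called Sqstm1 higher (adjusted p = 0.0441). Of 42 proteasome genes 20 rose, none of them in all 5 scalings, and 11 fell, 5 in all 5. Psmd5 (edgeR log2 fold change −2.22, SE 0.16, adjusted p = 3.48e-08) and Psme4 (log2 fold change −1.58, SE 0.14, adjusted p = 1.6e-07) fell. Psma7 rose (edgeR log2 fold change 1.16, SE 0.14, adjusted p = 3.64e-06; −0.48 under ribosomal scaling).

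Pmaip1 (edgeR log2 fold change 3.36, SE 0.25, adjusted p = 4.17e-08) and Gdf15 (log2 fold change 3.24, SE 0.41, adjusted p = 6.55e-06) rose, among 15 of 30 p53 targets that rose and 6 that fell (3 and 22 under ribosomal scaling). Cdkn1a at 153 ± 38.9 CPM and Mdm2 at 127 ± 32.9 were not called (edgeR adjusted p = 0.256 and 0.522). Their log2 fold changes of 0.22 and 0.13 turned to −1.39 and −1.48 under ribosomal scaling. Top2a fell 10.4-fold to 52.0 ± 6.52 CPM (edgeR log2 fold change −3.37, SE 0.19, adjusted p = 5.47e-09) and Top2b 2.36-fold (log2 fold change −1.24, SE 0.12, adjusted p = 3.39e-07). Of 30 mitotic genes 26 fell and 1 rose, with Ccna2 and Cdk1 down 9.26-fold and 8.04-fold (edgeR adjusted p = 7.79e-08 and 2.85e-08). Of 37 DNA replication genes 23 fell and 3 rose, and of 45 histone genes 38 rose and 3 fell. The histone median of 2.08 stood against 1.76 in the lowest of 5 groups of all tested genes by level. Under ribosomal scaling 36 replication genes fell and none rose, and 18 histone genes rose and 5 fell. Mcl1 (7.04-fold), Bcl2l1 (4.44-fold) and the metallothionein gene Mt1 (2.7-fold) were lower (edgeR adjusted p = 4.04e-07, 1.46e-07 and 3.45e-05), and Fosb and Fos were higher by 5.06 and 4.39 on the log2 scale (adjusted p = 1.13e-08 and 0.00258). The value of Fos was 6.03 without DMSO 1 and 3.80 without CFZ-DOX 3. Of 76 ribosomal protein genes 75 rose (median log2 fold change 1.66) and of 79 respiratory chain genes 69 rose and 2 fell (median 1.35), 9 and 5 of the risen ones in all 5 scalings. Adjusted over the list alone, 27 mitotic genes fell and 39 histone and 70 respiratory chain genes rose, and the other list counts given here for CFZ-DOX were the same.

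Camera called 7 of 23 lists for CFZ-DOX against DMSO, and none held with an estimated correlation: ribosomal protein genes up (adjusted p = 0.642 with an estimated correlation), respiratory chain up (0.85), histones up (0.326), haematopoietic markers up (0.326), extracellular matrix up (0.85), mitosis down (0.494) and DNA replication down (0.85). The extracellular matrix call was also lost without CFZ-DOX 1 (adjusted p = 0.111). The haematopoietic list had 5 of 5 tested members higher, but it held 12 markers, and Cd79a was tested only for its counts with doxorubicin. Its camera call was lost with replicates 1 and 2 only (adjusted p = 0.0516). Other splits of these 6 libraries gave up to 12 lists.

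The comparison of CFZ-DOX with CFZ shows what doxorubicin added to carfilzomib. Much of the carfilzomib response was lower: Hmox1 was 34.5-fold lower than with CFZ alone, Slc7a11 24.3-fold and Osgin1 27.1-fold, all in all 5 scalings (edgeR adjusted p = 8e-09, 1.11e-09 and 4.55e-08). Of 24 heat shock genes 20 were lower and 1 higher, of 42 proteasome genes 29 lower and 4 higher, and of 24 NRF2 targets 15 lower and 5 higher. In all 5 scalings 16, 18 and 13 of these were lower and none higher. Over all genes 6722 were higher and 6144 lower, 5410 and 4243 by at least 2-fold (edgeR quasi-likelihood test, adjusted p under 0.05).

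The list counts given here for this comparison were the same when adjusted over the list alone. The largest rises, in all 5 scalings, were again in genes nearly silent without doxorubicin, such as Btnl9 (edgeR log2 fold change 7.17, SE 0.52, adjusted p = 3.03e-08) and Slc10a1 (log2 fold change 6.20, SE 0.47, adjusted p = 4e-08). Others were Jsrp1 (edgeR log2 fold change 5.81, SE 0.33, adjusted p = 4.82e-09) and the myosin gene Myo1a (log2 fold change 5.60, SE 0.36, adjusted p = 1.13e-08). Besides Hmox1, the largest falls were those of Ccnq (edgeR log2 fold change −5.05, SE 0.31, adjusted p = 8.64e-09) and Chac1 (log2 fold change −4.80, SE 0.33, adjusted p = 1.89e-08). Osgin1 (edgeR log2 fold change −4.76, SE 0.36, adjusted p = 4.55e-08; −5.40 without CFZ-DOX 3) and Cebpb (log2 fold change −4.62, SE 0.37, adjusted p = 6.7e-08) came next. The chaperone genes Hsph1 (edgeR log2 fold change −3.57, SE 0.19, adjusted p = 3.17e-09), Dnajb1 (log2 fold change −3.51, SE 0.29, adjusted p = 9.56e-08) and Ptges3 (log2 fold change −3.65, SE 0.19, adjusted p = 2.84e-09) were lower. So were the proteasome genes Psmd5 (edgeR log2 fold change −2.84, SE 0.16, adjusted p = 5.53e-09), Psme4 (log2 fold change −2.62, SE 0.14, adjusted p = 3.09e-09) and Psmd11 (log2 fold change −2.45, SE 0.17, adjusted p = 2.08e-08). Sqstm1 was 9.75-fold lower, Trib3 22.7-fold, Phlda3 11.4-fold, Mdm2 4.39-fold and Cdkn1a 2.29-fold (edgeR adjusted p = 5.06e-09, 4.78e-09, 8.6e-09, 1.71e-07 and 1.69e-05). Ubb (edgeR adjusted p = 0.33), Hspa1a (0.4) and Hspa1b (0.382) were not called, but without CFZ-DOX 3 Hspa1a and Hspa1b were lower (log2 fold change −1.44 and −1.21, adjusted p = 0.000116 and 4.35e-05). Under ribosomal scaling all 3 genes were lower, Ubb with a log2 fold change of −1.77, and Ubb was lower with library size too (adjusted p = 0.0324).

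Of 30 p53 targets 19 were lower and 4 higher, and of 30 integrated stress response genes 18 and 5. Histone genes were higher (41 of 45, 28 in all 5 scalings), as was E2f2 (edgeR log2 fold change 3.04, SE 0.17, adjusted p = 3.74e-09). Some of these histone genes, Hist1h3b among them, were tested only for their counts with doxorubicin. Ribosomal protein genes (75 of 76), respiratory chain genes (71 of 79, with Uqcr11 at 2.28, edgeR adjusted p = 7.88e-08) and extracellular matrix genes (23 of 30) took a larger part of the counts, 9, 11 and 3 of them higher in all 5 scalings. Mcl1 and Top2a were 7.73-fold and 6.05-fold lower (edgeR adjusted p = 2.42e-07 and 2.09e-08). Camera called 12 lists, 7 up and 5 down, and with an estimated correlation none held. The smallest adjusted p with an estimated correlation was 0.21, for heat shock, NRF2, histones, haematopoietic and muscle markers. It was 0.363 for the integrated stress response, 0.545 for ribosomal protein and 0.589 for respiratory chain genes, 0.774 for proteasome, p53 and contractile genes and 0.775 for extracellular matrix. Upper-quartile scaling gave 8618 genes higher and 4205 lower and ribosomal scaling 2204 and 10912, and other splits of these 6 libraries gave up to 13 lists.

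On top of doxorubicin, carfilzomib still raised Ubb and HSP70 genes strongly, while with TMM scaling it changed few other stress genes. Hspa1b rose 12.3-fold over DOX alone, Ubb 11-fold, Hspa1a 10.8-fold and Hspa8 10.2-fold, all in all 5 scalings (edgeR adjusted p = 0.000164, 1.82e-07, 0.000465 and 9.79e-07). Without CFZ-DOX 3 the log2 fold change of Hspa1b went from 3.63 to 2.78 and that of Hspa1a from 3.43 to 2.40. Of the 24 heat shock genes 5 rose and 2 fell, of 42 proteasome genes 8 rose and 3 fell, and of 24 NRF2 targets 2 rose and 2 fell, with the same counts adjusted over each list alone. Under ribosomal scaling 14 heat shock genes, 35 proteasome genes and 16 NRF2 targets were lower, and 3 heat shock genes but no proteasome gene or NRF2 target higher. Over all genes 1722 were higher and 2005 lower than with DOX, 630 and 570 by at least 2-fold (edgeR quasi-likelihood test, adjusted p under 0.05). The spread behind these counts was estimated over all 12 libraries, and replicates with doxorubicin differed more than those without. Fitted to the 6 libraries of this comparison alone, 461 genes were higher and 657 lower.

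Ubb (ENSMUSG00000019505, GRCm39 chromosome 11, 62441997 to 62444039, plus strand) stood at 157 ± 30.8 CPM with DOX and 1719 ± 270 with both drugs (SD, n = 3). Hspa8 went from 278 ± 76.2 to 2830 ± 371 CPM. The pseudogene Gm15459 takes a count of 45.9 to 50.1% of that of Hspa8 in these libraries and Gm1821 7.89 to 9.5% of that of Ubb, so the absolute levels of both genes are uncertain. Ppp1r15a rose 4.7-fold (edgeR log2 fold change 2.23, SE 0.25, adjusted p = 9.26e-05) and Ddit3 3-fold (log2 fold change 1.59, SE 0.27, adjusted p = 0.00134), the latter without a call under ribosomal scaling. The chemokine gene Cxcl1 rose too (edgeR log2 fold change 3.03, SE 0.60, adjusted p = 0.00525), by 1.89 on the log2 scale without CFZ-DOX 3. Dnajb1 rose 2.01-fold (edgeR adjusted p = 0.016), a call lost without DOX 1 or DOX 2 (adjusted p = 0.055 and 0.0531) and under library size (0.132) or ribosomal scaling (0.579).

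Psmd4 and Psmc4 rose 1.55-fold and 1.51-fold (edgeR adjusted p = 0.00643 and 0.00721), with log2 fold changes of 0.64 and 0.59 that turned to −0.10 and −0.14 under ribosomal scaling. Psma5 (edgeR log2 fold change −0.56, SE 0.12, adjusted p = 0.00585) and Psmg2 (log2 fold change −0.75, SE 0.15, adjusted p = 0.00403) fell in all 5 scalings. Psmb5 was level with DOX (edgeR log2 fold change 0.00, SE 0.15, adjusted p = 0.992; −0.74 under ribosomal scaling), and Nfe2l1 was not called (adjusted p = 0.151, and 0.04 with the replicate block, lower). Nfe2l1 was lower with library size (adjusted p = 0.00615), with ribosomal scaling (5.97e-05) and without CFZ-DOX 1 (0.0481) too. Hmox1 at 41.3 ± 16.8 against 26.3 ± 9.50 CPM was not called (edgeR adjusted p = 0.0926, and 0.0169 with the replicate block, higher). It was higher with DESeq2 (adjusted p = 0.0491) and without CFZ-DOX 2 (0.032) or DOX 3 (0.0195) too. Sqstm1 was not called either (edgeR log2 fold change 0.14, SE 0.17, adjusted p = 0.585; −0.60 under ribosomal scaling), and Srxn1 fell in all 5 scalings (log2 fold change −0.59, SE 0.13, adjusted p = 0.00643).

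Both topoisomerase II genes were lower than with DOX alone, Top2a 3.7-fold at 52.0 ± 6.52 against 192 ± 42.7 CPM (edgeR log2 fold change −1.89, SE 0.18, adjusted p = 2.55e-05) and Top2b 1.98-fold (log2 fold change −0.99, SE 0.12, adjusted p = 0.000112), in all 5 scalings. Of 30 mitotic genes 12 fell, including Cdk1 (edgeR log2 fold change −2.08, SE 0.21, adjusted p = 3.7e-05) and Aurkb (log2 fold change −1.54, SE 0.14, adjusted p = 2.52e-05). Of 37 DNA replication genes 9 fell and 2 rose (30 fell and none rose under ribosomal scaling; 11 and 2 adjusted over the list alone), with Pcna down 1.97-fold (edgeR adjusted p = 0.000429). The largest falls were those of the calmodulin gene Calm2 (edgeR log2 fold change −2.14, SE 0.18, adjusted p = 1.36e-05), Nynrin (log2 fold change −2.13, SE 0.29, adjusted p = 0.00033) and Apln (log2 fold change −2.13, SE 0.24, adjusted p = 9.4e-05). Arxes2 (edgeR log2 fold change −2.08, SE 0.26, adjusted p = 0.000161), Cdk1 and the thrombomodulin gene Thbd (log2 fold change −2.07, SE 0.35, adjusted p = 0.00122) followed. The metallothionein genes Mt1 and Mt2 fell 2.47-fold and 2.39-fold (edgeR adjusted p = 0.00125 and 0.00504). All 76 ribosomal protein genes rose, with a median log2 fold change of 0.75 (Rpl13a 0.98, edgeR adjusted p = 0.000474), and none did under ribosomal scaling, where the median of all genes lay 0.76 lower.

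Camera called 7 of 23 lists for carfilzomib on top of doxorubicin, and none held with an estimated correlation. The call of mitosis, down (adjusted p = 1.84e-08), had an adjusted p = 0.461 with an estimated correlation, as had ribosomal protein genes and haematopoietic markers, both up. Respiratory chain, heat shock, NF-κB and extracellular matrix genes, all up, had an adjusted p = 0.872 with an estimated correlation. The heat shock call was lost without DOX 3 (adjusted p = 0.363), the NF-κB call without CFZ-DOX 3, DOX 2 or DOX 3 (0.112, 0.0533 and 0.1). The haematopoietic call was lost without CFZ-DOX 3 or DOX 2 (adjusted p = 0.0604 and 0.0533) and the extracellular matrix call without CFZ-DOX 1, DOX 2 or DOX 3 (0.939, 0.104 and 0.677). Without DOX 2 only 4 lists were called, with replicates 1 and 2 only 3, and with the replicate number as a block 11, and other splits of these 6 libraries gave up to 13. Genes higher and lower were 2289 and 1642 with DESeq2-type size factors, 667 and 2820 with library size, 2625 and 1433 with upper-quartile and 135 and 8660 with ribosomal scaling, and 135 and 1388 were called the same way in all 5.

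The interaction term asks whether the effect of both drugs departs from the sum of their single effects on the log2 scale. In 4 lists of genes raised by carfilzomib the combination lay below that sum for most members. The interaction was negative for 33 of 42 proteasome genes, 19 of 24 heat shock genes, 17 of 24 NRF2 targets and 20 of 30 p53 targets, and positive for 0, 1, 0 and 0 of them. The 0 counts were from edgeR and held at an unadjusted p under 0.05 and with limma-voom, while DESeq2 gave 1 positive NRF2 target. Adjusted over the list alone the negative counts were 34, 19, 19 and 24, and in all 5 scalings 26, 17, 15 and 18. Fewer members of other stress lists were called: the interaction was negative for 8 and positive for 3 of 30 integrated stress response genes, negative for 8 and positive for 2 of 21 autophagy genes, and negative for 5 of 24 unfolded protein response and 5 of 20 NF-κB genes. Over all genes it was positive for 1408 and negative for 1862 (edgeR quasi-likelihood test, adjusted p under 0.05).

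Of the named genes Hmox1 departed most (edgeR log2 fold change −4.61, SE 0.39, adjusted p = 1.17e-05). Fas (edgeR log2 fold change −4.05, SE 0.47, adjusted p = 0.000112), Calr3 (log2 fold change −3.82, SE 0.26, adjusted p = 2.07e-06) and Atf3 (log2 fold change −3.77, SE 0.53, adjusted p = 0.000383; −4.42 without CFZ-DOX 3) came next among negative interactions. They were followed by Gdf15 (edgeR log2 fold change −3.44, SE 0.52, adjusted p = 0.000639), Srxn1 (log2 fold change −3.38, SE 0.19, adjusted p = 4.57e-07), Sqstm1 (log2 fold change −3.37, SE 0.25, adjusted p = 3.74e-06) and Slc7a11 (log2 fold change −3.31, SE 0.22, adjusted p = 2.07e-06). Of the chaperone genes, Cryab (edgeR log2 fold change −2.80, SE 0.32, adjusted p = 0.000108), Hsph1 (log2 fold change −2.63, SE 0.25, adjusted p = 2.97e-05), Hsp90aa1 (log2 fold change −2.21, SE 0.28, adjusted p = 0.000179) and Dnajb1 (log2 fold change −2.09, SE 0.38, adjusted p = 0.00193) had negative interactions. So had the proteasome genes Psma5 (edgeR log2 fold change −1.73, SE 0.17, adjusted p = 3.88e-05) and Psmd11 (log2 fold change −1.72, SE 0.23, adjusted p = 0.00028) and their regulator Nfe2l1 (log2 fold change −1.22, SE 0.24, adjusted p = 0.0035). Mdm2 (edgeR log2 fold change −1.76, SE 0.26, adjusted p = 0.000503) and Cdkn1a (log2 fold change −1.36, SE 0.24, adjusted p = 0.00159) had them too.

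Hspa1a and Hspa1b had no called interaction (edgeR adjusted p = 0.751 and 0.531), with log2 values of 0.34 and 0.52 that turned to −0.69 and −0.32 without CFZ-DOX 3. Those of Ubb (edgeR log2 fold change 0.96, SE 0.24, adjusted p = 0.0135) and Hspa8 (log2 fold change 1.03, SE 0.29, adjusted p = 0.0211) were positive. Library size (adjusted p = 0.0507) and ribosomal scaling (0.585) ended the call of Ubb, and ribosomal scaling that of Hspa8 (0.0546). Leaving out 1 library ended that of Hspa8 in 6 of 12 cases (CFZ 1, CFZ 2, CFZ-DOX 1, DMSO 2, DMSO 3 and DOX 2; adjusted p up to 0.0691). Ddit3 was not called (adjusted p = 0.524) but was negative without CFZ-DOX 3 (edgeR adjusted p = 0.00657). Positive interactions were largest for Id3 (edgeR log2 fold change 3.18, SE 0.38, adjusted p = 0.000138), Gas1 (log2 fold change 3.15, SE 0.43, adjusted p = 0.000319) and Lars2 (log2 fold change 3.05, SE 0.38, adjusted p = 0.000177). Next were Mir6236 (edgeR log2 fold change 2.93, SE 0.53, adjusted p = 0.00195), Siglecg (log2 fold change 2.86, SE 0.36, adjusted p = 0.000177) and Nab2 (log2 fold change 2.61, SE 0.27, adjusted p = 6.02e-05). Whether the reads on Lars2 and Mir6236 come from ribosomal RNA was not tested. Nab2 stood at 90.8 ± 17.3 CPM with DMSO and at 14.6 ± 3.58, 16.1 ± 1.19 and 15.8 ± 2.59 with CFZ, DOX and CFZ-DOX.

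The 982 genes that CFZ alone raised at least 2-fold had a median log2 fold change of 1.47 without and 0.27 with doxorubicin, where 184 were higher and 36 lower, and 549 of them had a negative interaction. The 1083 genes that it lowered at least 2-fold went from a median of −1.42 to −0.24, and 563 had a positive interaction. These genes were chosen by the first of the paired values, which by itself pulls the second towards 0. Of 1276 genes called in both CFZ comparisons 307 were called in opposite directions, 206 higher with CFZ alone and lower on top of DOX and 101 the other way.

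**Figure D3:**
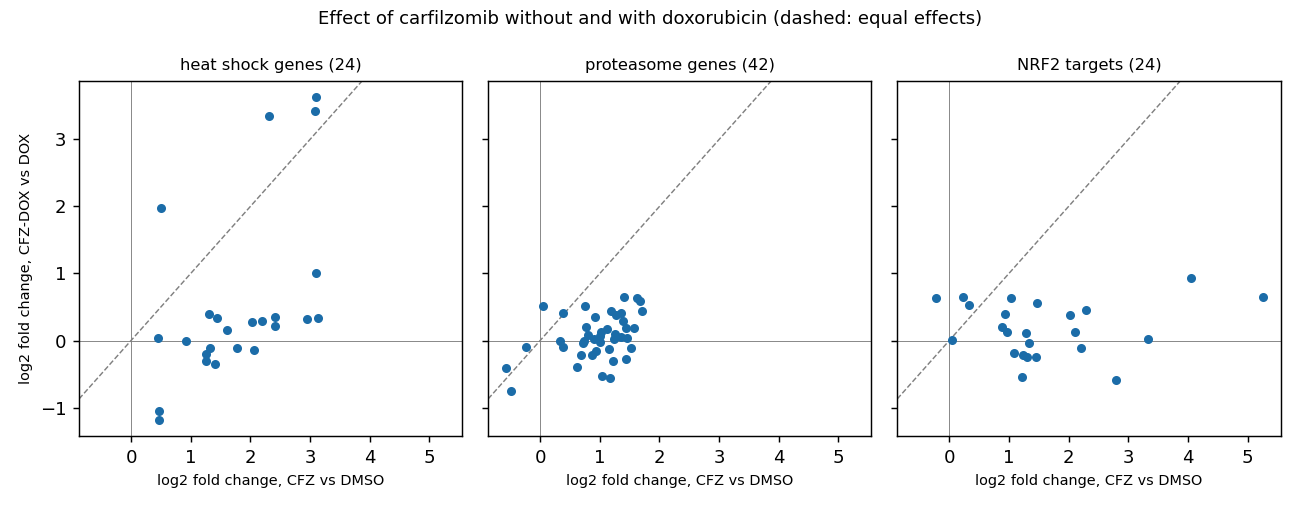
Log2 fold change of each heat shock (24), proteasome (42) and NRF2 target gene (24) for CFZ vs DMSO (horizontal axis) and for CFZ-DOX vs DOX (vertical axis), with a dashed line of equal effects. Most points lie under the line, and the interaction was negative for 19, 33 and 17 of the genes, while 4 heat shock genes lie above it, Hspa8 among them, and Hspa1a and Hspa1b only when CFZ-DOX 3 is included.

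Camera called 16 of 23 lists for the interaction, 8 up and 8 down. With an estimated correlation the NRF2 (adjusted p = 0.0115) and heat shock lists (0.0181) held. The other lists called down had an adjusted p of 0.101 (p53 targets and autophagy), 0.177 (integrated stress response), 0.184 (proteasome), 0.434 (NF-κB) and 0.49 (unfolded protein response) with an estimated correlation. The lists called up had 0.177 (histones), 0.383 (DNA replication), 0.415 (mitosis), 0.434 (ribosomal protein genes and fibroblast markers), 0.442 (contractile genes), 0.49 (respiratory chain) and 0.666 (extracellular matrix). The calls of the unfolded protein response (without CFZ-DOX 3 or DOX 1, adjusted p = 0.118 and 0.06), contractile genes (without DOX 3, 0.0505) and extracellular matrix (without CFZ-DOX 1 or DOX 3, 0.105 and 0.0916) rested on single libraries. Without CFZ 3 the interaction was called for 2149 genes in place of 3270, upper-quartile scaling gave 2195 positive and 1321 negative, ribosomal scaling 245 and 5313, and in all 5 scalings 244 were positive and 1095 negative.

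Genomic span, the distance from a gene's start to its end, went with the change in the libraries with doxorubicin. Tested genes were ordered by span and parted into 10 groups of equal size. In the group with the shortest span, up to 1.35 kb, the median log2 fold change was 0.92 for DOX and 1.48 for CFZ-DOX against DMSO, and in the group with the longest, from 99 kb, it was −0.56 and −0.88. For CFZ against DMSO these medians were −0.01 and −0.03. Across genes, which are not independent replicates, Spearman's rho of span and fold change was 0.07 for CFZ, −0.32 for DOX and −0.26 for CFZ-DOX against DOX. Medians fell with exon length too. From the shortest to the longest of 5 groups they went from 0.88 to −0.51 for DOX. For CFZ-DOX against DOX they went from 0.32 to −0.14. By level, the median for DOX was 1.4 in the lowest of 5 groups, −0.37 in the next to highest and 0.07 in the highest. Span, exon length and level were not separated, so the trend is not shown to belong to span.

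**Figure D4:**
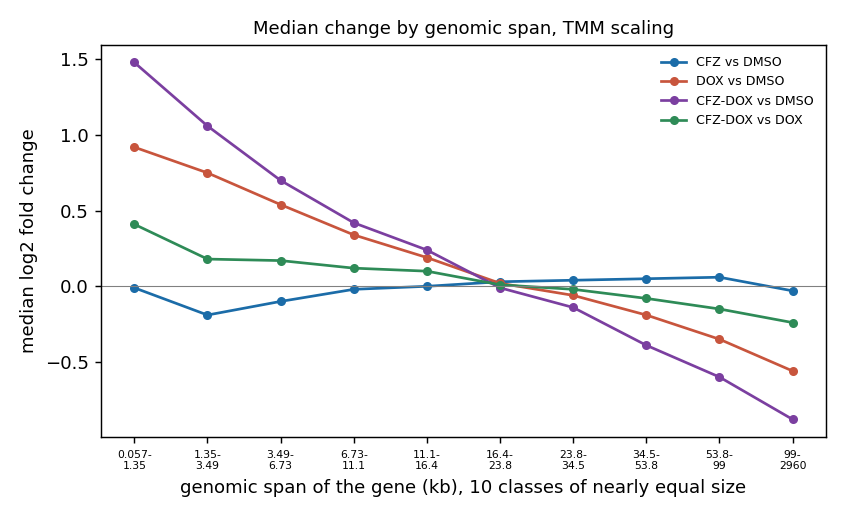
Median log2 fold change (vertical axis) of genes in 10 groups of genomic span from shortest to longest (horizontal axis) in 4 comparisons with TMM scaling. The line of CFZ vs DMSO stays between −0.19 and 0.06, and that of DOX vs DMSO goes from 0.92 to −0.56.

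Each drug alone was compared with the same 3 DMSO libraries. Across genes, which are not independent replicates, the log2 fold changes of CFZ and DOX had a Pearson r of 0.08, where unchanged groups simulated against these controls gave 0.48 on average, and a covariance of 0.127, against 0.114 on average and up to 0.127 in 20 simulations. No gene changed in the simulations, so their r comes from the shared controls alone and cannot be set against 0.08. The covariance can be compared, and it lay at the upper end of the simulated values. Without DMSO 1, 2 or 3 the r was 0.148, 0.162 and 0.173. Both drugs changed 3159 genes: 672 were higher with both and 1033 lower with both, where independent lists would share 867.1 and 749.9, and 902 were higher with CFZ and lower with DOX and 552 the reverse, against 752.1 and 864.6. With 3 controls no split into parts of 2 was possible, so part of any excess may come from the shared controls.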

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

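The tests of scaling and of missing carfilzomib, of genomic span, of evenly spread genomic DNA, of the dispersion of other splits and of the median under ribosomal scaling were chosen only after the result was seen. The scalings themselves were chosen before.

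The effect of CFZ differed without and with DOX: 3270 genes and 16 gene lists had an interaction, and 307 genes were called in opposite directions in the 2 CFZ comparisons. Of these lists only 2, heat shock and NRF2, held with an estimated correlation. Of 40 splits of the 12 libraries 1, the real one, gave as many genes (highest of the others 0) and 1, again the real one, as many lists (highest of the others 15), a share of 0.025. The other splits put libraries with and without DOX into the same group, which raised the common dispersion from 0.0395 to at least 0.234. Few calls were to be expected from them by that alone, so these counts say little about chance.

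The effect of CFZ on 90 heat shock, proteasome and NRF2 genes was smaller with DOX: their median log2 fold change was 1.25 without and 0.10 with it. Scaling is argued against, since the median interaction of −1.10 lay below all of 10000 lists matched on mean expression (−0.38 to 0.35) and stayed between −1.78 and −0.93 over 5 scalings. Missing carfilzomib is argued against too, since each of Ubb, Hspa8 and Hspa1b was at least 5.02 times higher in the lowest CFZ-DOX library than in the highest DOX library. A candidate explanation for a part of it is that CFZ on top of DOX lowered long genes relative to short ones in general. Over the 982 genes raised at least 2-fold by CFZ the change on top of DOX fell with genomic span (Spearman rho −0.27, permutation p = 1e-05, the smallest that 100000 permutations can give). This was about as over all 16648 genes tested (−0.26). The permutations treat genes as independent replicates, which they are not, so this p does not measure the spread between libraries. Span was not separated from exon length or level, so this trend is not shown to belong to span. From the shortest to the longest of 4 span groups the medians were 1.59, 1.49, 1.45 and 1.38 without and 0.56, 0.36, 0.24 and 0.04 with DOX, so span leaves most of the drop open, and a biological interaction of the drugs stays an untested hypothesis.

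Ribosomal protein and respiratory chain transcripts took a larger part of the counts with DOX. The median of 0.91 of ribosomal protein genes lay above 0.82, the upper bound of the central range of 10000 lists matched on exon length and level. The highest of these lists reached 0.90. They were drawn gene by gene, while ribosomal protein genes moved together, with an estimated correlation of 0.882. Their range is therefore too narrow to tell whether a general trend with exon length and level was the whole of it. The median of those lists was 0.72, so the trend may account for a large part. The lists were not matched on genomic span. All tested genes of the shortest of 10 span groups had a median of 0.92 with DOX, so a trend with span stays open. Whether these transcripts rose or the others fell cannot be told apart, since the median of all genes was −0.73 when counts were scaled to ribosomal protein genes and the table holds no external standard.

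Genes of olfactory and vomeronasal receptors, which fibroblasts are not known to use, had 17.6 ± 4.45 CPM in all with DOX against 7.44 ± 0.0461 with DMSO (SD, n = 3). Depth is argued against, since at equal totals the lowest DOX library held 2863 more genes with a count than the highest DMSO library. Evenly spread genomic DNA is argued against only for silent genes near expressed genes. Their excess of counts per exon length within 10 kb downstream was at least 48.7 times that far from expressed genes in the 3 DOX libraries. Far silent genes rose too, from 1.51 ± 0.16 CPM per Mb of exon with DMSO to 3.26 ± 1.15 with DOX. An even background behind the receptor counts was therefore not tested. The excess was at least 1.48 times higher downstream than upstream, but silent genes had 13.1 CPM per Mb of exon downstream against 7.11 upstream with DMSO too, so that the side does not set DOX apart. Transcription running past the ends of expressed genes stays open, as do, without a known strand setting, reads from the opposite strand.

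With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Fitted to the 6 libraries alone, the real splits gave 7925 genes for CFZ, 10568 for DOX, 11275 for CFZ-DOX against DMSO, 11446 against CFZ and 1118 against DOX, and the highest of the others 0, 0, 0, 0 and 15, so 1 split each reached the real count. For gene lists the real splits gave 12, 5, 8, 12 and 10 and the highest of the others 16, 15, 12, 13 and 13, with 7, 10, 8, 3 and 4 of the 10 splits giving as many. In the 3 comparisons whose numbers pair the libraries, the 3 other splits that part as many pairs gave at most 0 genes, and 15, 11 and 5 lists for CFZ, DOX and CFZ-DOX against DOX. Each other split mixed both treatments on each side, which adds the treatment difference to the spread within a side. Few genes were to be expected by that alone. A part of the difference also stayed between the sides, from which lists can be called. These gene and list counts therefore say little about chance.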

How the results depend on the processing

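Of the alternatives given here, the fits of replicates 1 and 2 alone were chosen after the result was seen, and the others, ribosomal scaling among them, were planned. Of 261 gene and comparison pairs named, 234 were called, and 249 stayed on one side of the threshold whichever library was left out. Under ribosomal scaling 13 named values changed sign: for CFZ-DOX against DMSO Cdkn1a −1.39, Hmox1 −1.44, Hspa8 −0.49, Mdm2 −1.48, Psma7 −0.48 and Sqstm1 −1.42, for DOX against DMSO Cdkn1a −0.71, Gapdh −0.06 and Sqstm1 −0.82, and against DOX Psmb5 −0.74, Psmc4 −0.14, Psmd4 −0.10 and Sqstm1 −0.60. That follows from its construction, which lowers every gene of a comparison by nearly the same amount.

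Counts moved by over 1.5 times as follows, and except where stated the cause was not tested. An adjusted p under 0.01 left 2827 genes for CFZ, 1577 for CFZ-DOX against DOX and 1393 for the interaction, and a test against 1.5-fold 1489, 384 and 925, as stricter rules must lower them. The 6 libraries alone gave 7925 for CFZ and 1118 against DOX. Such a fit uses the spread of its own libraries, which differed between groups. The chi-square per degree of freedom was 13.86 to 32.47 within DMSO and CFZ and 51.87 to 125.3 within DOX and CFZ-DOX. Ribosomal scaling gave 8795 against DOX, 5558 for the interaction and 8 lists for DOX. The replicate block gave 5031 genes for the interaction, 7 lists for DOX and 11 against DOX. It changed the calls of Hmox1, Hspa1b and Mdm2 for DOX and of Hmox1 and Nfe2l1 against DOX, and no other named call in the paired comparisons. For CFZ-DOX with DMSO (r 0.29, 0.06 and 0.08) and CFZ (0.26, 0.02 and 0.10) the libraries share only a number, although all 12 correlated best with their own, and the block gave 13115 and 13445 genes. In the 3 paired comparisons the block gave 6124 genes for CFZ, 12112 for DOX and 5524 against DOX, in place of 4797, 11223 and 3727. With an estimated correlation 6 lists were called for CFZ, 0 for DOX, 0 for CFZ-DOX against DMSO, 0 against CFZ, 0 against DOX and 2 for the interaction, and with fry 14 for DOX, 17 for CFZ-DOX against DMSO and 4 against DOX. Replicates 1 and 2 alone gave 3 lists against DOX.

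Leaving out 1 library at a time gave 3258 to 3676 genes for CFZ, 10462 to 11725 for DOX, 12204 to 12772 for CFZ-DOX against DMSO, 12574 to 13117 against CFZ, 2701 to 4606 against DOX and 2149 (without CFZ 3) to 4898 for the interaction. Lists were 12 to 13, 4 to 6, 6 to 9, 12 to 13, 4 (without DOX 2) to 10 and 14 to 16 in the same order. The correlation of CFZ and DOX fold changes went from 0.042 to 0.173, with the highest values, 0.148, 0.162 and 0.173, without DMSO 1, 2 and 3.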

Other observations

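The gene groups below were chosen only after the data were seen, so their camera tests are not evidence independent of that choice. Of 304 tested zinc finger genes named Zfp and a number, 202 fell and 23 rose with DOX, 172 and 3 of them in all 5 scalings, with a median log2 fold change of −1.12 (−1.97 to −0.75 over the scalings). Zfp638 went from 107 to 10.4 CPM (edgeR log2 fold change −3.35, SE 0.21, adjusted p = 2.35e-08). Camera gave an adjusted p = 1.65e-12 for this group, and adjusted p = 0.441 with an estimated correlation. With CFZ 43 of these genes rose and 24 fell.

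Of 27 Hox genes, which set positional identity, 9 fell with CFZ 7 of them in all 5 scalings, and none rose in edgeR (1 at an unadjusted p under 0.05, 0 with DESeq2 and 0 with limma-voom). Hoxa2 went from 11.1 to 1.83 CPM and Hoxa3 from 23.1 to 4.92 (edgeR log2 fold change −2.59 and −2.23, SE 0.19 and 0.18, adjusted p = 8.41e-07 and 1.23e-06). Camera gave an adjusted p = 0.000205 for the group, and adjusted p = 0.534 with an estimated correlation. With DOX 12 Hox genes rose and 3 fell, with a median of 0.26 that went from −0.58 to 0.63 over the scalings. Of 8 cathepsin genes, which encode lysosomal proteases, 6 rose with DOX, 1 in all 5 scalings, and the median of 1.15 lay between 0.23 and 1.53 over them. Camera gave an adjusted p = 0.0475 for the cathepsins, and adjusted p = 0.441 with an estimated correlation. Of 17 glycolytic genes 13 rose and 1 fell with DOX, with a median of 0.68 that went from −0.20 to 1.06 over the scalings.

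Lars2 stood at 101 ± 9.07 CPM with DMSO, 101 ± 31.9 with CFZ, 169.8 ± 55.2 with DOX and 1407 ± 340 with CFZ-DOX, and Mir6236 at 1.44 ± 0.0706, 1.60 ± 0.756, 2.28 ± 1.11 and 19.5 ± 4.51 (SD, n = 3). ENSMUSG00000119584, the ID with most counts among those without a symbol, was highest with CFZ-DOX too. It had 2810 ± 800, 2103 ± 1120, 3259 ± 709 and 4889 ± 849 CPM of the library total in the same order. Whether reads on these IDs come from ribosomal RNA was not tested, so the rises are not shown to be regulation of the named genes.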
